A study of Mus musculus with 6 samples.

How the data were processed

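RNA was measured by sequencing in neural progenitors that had been differentiated from mouse embryonic stem cells (mESCs) of 2 genotypes, with 3 libraries from a line labelled flox/flox, the control, and 3 from a line labelled -/- for Dmrta2. The labels describe the 3 samples of a genotype as biological replicates of 1 line each. Genotype and line are therefore not separable, and the p-values measure the spread between the samples of a line. Per the labels' protocols, RNA was taken on day 8 of differentiation and libraries were made from 1 µg with a stranded poly(A) mRNA kit.

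The deposited values are raw read counts per Ensembl gene in 1 table for all 6 libraries. Per the submitters' processing notes, BWA 0.5.9 and featureCounts 1.4.6 were used with the mouse build mm10 (GRCm38). The name of the table says that duplicate reads were marked. Whether marked reads were counted, the annotation release, the strand setting of the counting and the treatment of multiply mapped reads are not given in the sources used here. A gene that overlaps another on either strand can therefore hold reads of its neighbour. Of 129 named genes, 6 have at least 20% of their exonic bases under exons of another gene: Nrarp (79.4%), Ccdc3 (69.1%), Hes5 (31.8%), Cdkn1c (30.7%), Shh (28.3%) and Slc32a1 (24.9%). The near-identical paralogs Dsg1a and Dsg1b are uncertain because reads can be shared between them.

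Columns of the table name the genotype and a letter from A to C, while the labels number the replicates, so columns were assigned to a group and not to a numbered sample. Libraries are named here by genotype and column letter, and 0 columns of sample values were left out. Total counts were 29820515, 26124118 and 24565560 in flox/flox A, B and C and 39646793, 35182356 and 29031604 in -/- A, B and C. Levels are given in CPM, counts scaled by library size, so that a level of 1 CPM stands for at least 24.6 reads in a library. Symbols, positions and biotypes were taken from GENCODE release M21 on GRCm38, by gene identifier. Of the 48526 identifiers, 48058 had a symbol, and those without held between 0.196% and 0.226% of a library's counts. Libraries of 1 group differed by more than sampling noise, with a chi-square per gene between 5.47 and 29.8, so all 6 entered as separate samples.

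Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) on the deposited counts. Genes were kept with filterByExpr (minimum count 10, minimum total count 15), TMM scaling factors were applied, and the model held the group alone. P-values were adjusted by the Benjamini-Hochberg method over the 20549 genes tested, with a threshold of 0.05. "Rose" and "fell" denote genes past that threshold that were higher or lower in the libraries labelled -/-. Fold changes are log2 values with the standard error (SE) of the fitted coefficient, and levels are TMM-normalised CPM given as mean ± SD over n = 3 libraries.

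A set of 25 gene lists was written before the data were examined. They covered neural progenitors, the Notch pathway, Notch effectors, proneural and neurogenic factors, postmitotic neurons, dorsal telencephalon, cortical hem and choroid plexus, ventral telencephalon, diencephalon with midbrain, hindbrain and spinal cord, eye field and retina, Cajal-Retzius cells, cortical layer neurons, S phase, G2/M phase, cell cycle exit, pluripotency, mesoderm and endoderm, neural crest and placode, glia, Wnt targets, Hedgehog targets, BMP targets, p53 and apoptosis, hypoxia and glycolysis, and the Dmrt family. The lists hold 430 distinct genes, 45 of them in more than 1 list. Each list was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 25 lists. Camera was repeated with a correlation estimated from the data, and fry, a rotation test that does not compare a list with other genes, was run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone.

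The genes named in the text follow a rule that was also set before the data were examined. It takes Dmrta2, its chromosomal neighbours Elavl4 and Faf1, a panel of 14 neural genes, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM, groups that do not overlap and a symbol other than a Gm number or Rik clone name, and up to 3 members per list and direction with the smallest adjusted p. Genes outside the rule are described as added, meaning that they were chosen after their values were seen. Some genes that the rule selects are not reported here by name, and they stay in the tests and in the counts of the lists.

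Alternatives set before the data were examined were DESeq2 size factors or upper-quartile scaling in edgeR, no low-count filter, a filter of 1 CPM in at least 3 libraries, each library left out in turn, a DESeq2 1.42.0 Wald test, limma-voom, and a threshold of 0.01. A block on the replicate number was also planned and was not run, since the columns carry letters. The letter was used as the block instead, as an alternative chosen after seeing the data. The pairing was checked with the correlation, over genes, of the deviations of same-letter libraries from their group means. It was 0.27 for A, 0.10 for B and 0.26 for C, all above 0.1. The blocked value is given where it changes the call of a list or of a gene named by the rule. Blocked counts of list members are given for some lists only. Also chosen after seeing the data were the alternatives without the genes of chromosome 11 and with the chromosome 11 median as an offset. The list of imprinted genes in the closing section was written after the values of 49 of its 53 genes had been seen. A first list had been typed before those values were looked up but after 7 of its genes had been noticed, and 6 of its genes were then left out of the later list; its other 48 genes serve as a separate check.

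The scripts were tested on simulated counts for the same comparison, drawn for 20300 tested genes from the observed means and library sizes. Of the genes changed 1.5-fold (67 genes), 68.7% were recovered with the right sign, against 94.0% of those changed 2-fold (67 genes) and 100% of those changed 4-fold (66 genes). Of all calls in the simulation, 5.49% were unchanged genes. Camera gave the shifted list an adjusted p of 3.46e-21 and called 0 of 24 unshifted lists at the adjusted threshold. Genes were drawn independently of each other, and 18417 of them were unchanged. The simulation therefore cannot tell whether the preset correlation suits lists whose members vary together, or data with more changed genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.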

Results

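The series profiled RNA from neural progenitor cells made from mESCs, which differentiate into neural cells in adherent culture once serum and the cytokine LIF are withdrawn. Of the 6 libraries, 3 came from a flox/flox line, in which recombinase sites flank part of Dmrta2 and which served as the control, and 3 came from a line labelled -/-. The medium held LDN193189 (100 nM), an inhibitor of BMP receptors, and SB431542 (10 µM), an inhibitor of activin and TGF-beta receptors, until day 4. It held the Wnt pathway inhibitor XAV939 (1 µM) until day 6. The Hedgehog pathway inhibitor cyclopamine (1 µM) was given from day 2 until day 10 of the protocol, and RNA was taken on day 8. Total counts ran from 24565560 to 39646793 per library, and the common biological coefficient of variation between libraries of a group was 0.123. The comparison asks which genes depend on Dmrta2, a zinc finger transcription factor of the Dmrt family made in dorsal telencephalic progenitors, and whether its loss alters the balance between progenitors and neurons.

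Dmrta2 counts were higher in all 3 libraries labelled -/- than in any flox/flox library. Dmrta2 (ENSMUSG00000047143, GRCm38 chromosome 4, 109978053 to 109983687, plus strand) measured 85.2, 75.1 and 79.2 CPM in flox/flox A, B and C and 409, 414 and 439 CPM in -/- A, B and C. The difference was 2.40 ± 0.07 (log2, SE), or 5.27-fold, with an adjusted p of 2.0e-05 by edgeR's quasi-likelihood test. A higher count is not what loss of the whole gene would give. The count covers the whole gene, however, including any part outside the deleted one. The labels do not say which part was removed, so the count checks nothing about the deletion. All directions below are therefore those of the libraries labelled -/- against those labelled flox/flox. Of the neighbours of Dmrta2 on chromosome 4, Faf1 rose by 0.58 ± 0.06 (adjusted p = 0.000627, edgeR) and Elavl4, which encodes a neuronal RNA-binding protein, by 1.09 ± 0.23 (adjusted p = 0.00993, edgeR). Cdkn2c, on the far side of Faf1 (109660876 to 109667189), rose as well and is given below with the genes of cell cycle exit. The antisense gene Dmrta2os, added because it adjoins Dmrta2, rose from 5.57 ± 0.909 to 46.7 ± 3.17 CPM (SD, n = 3).

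In the libraries labelled -/-, 24 of 25 listed genes of neurogenesis and 26 of 30 of neurons rose (15 and 11 without flox/flox B), 18 of 23 genes of the cortical hem and choroid plexus and 6 of 11 BMP targets fell, and genes of the dorsal telencephalon moved in both directions. The proneural, neuron, hem and BMP lists were among 12 of 25 that passed in camera at the preset correlation between genes. Without flox/flox B the proneural and neuron lists passed at the preset correlation too (camera adjusted p = 6.66e-16 and 3.18e-09). With a correlation estimated from the data 0 of the 25 passed (3 at an unadjusted p under 0.05), and fry called 17. The proneural factor Neurog2 rose 5.22-fold, from 33.8 ± 14.6 to 176 ± 29.0 CPM (SD, n = 3). Bmp4, a ligand secreted from the dorsal midline, fell 16.1-fold (10.0-fold without flox/flox A), and Shh, the ventral midline ligand of the Hedgehog pathway, rose 21.3-fold.

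Of 20549 genes tested, 7250 (35.3%) passed the threshold, 3679 of them higher and 3571 lower. At an absolute log2 fold change of at least 1 there were 2341 genes, 984 higher and 1357 lower. Protein-coding genes made up 5975 of the calls, out of 14743 tested. The CPM of the groups did not overlap for 51.0% of the tested genes, where chance gives 10% for 3 libraries against 3. Without flox/flox B, 4717 genes passed, 2315 of them higher, and without -/- B the number of lower genes was 2342. The first principal component held 76.5% of the variance and placed flox/flox A, B and C at -62.4, -52.5 and -37.5 and the libraries labelled -/- between 38.0 and 68.5.

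**Figure D1:**
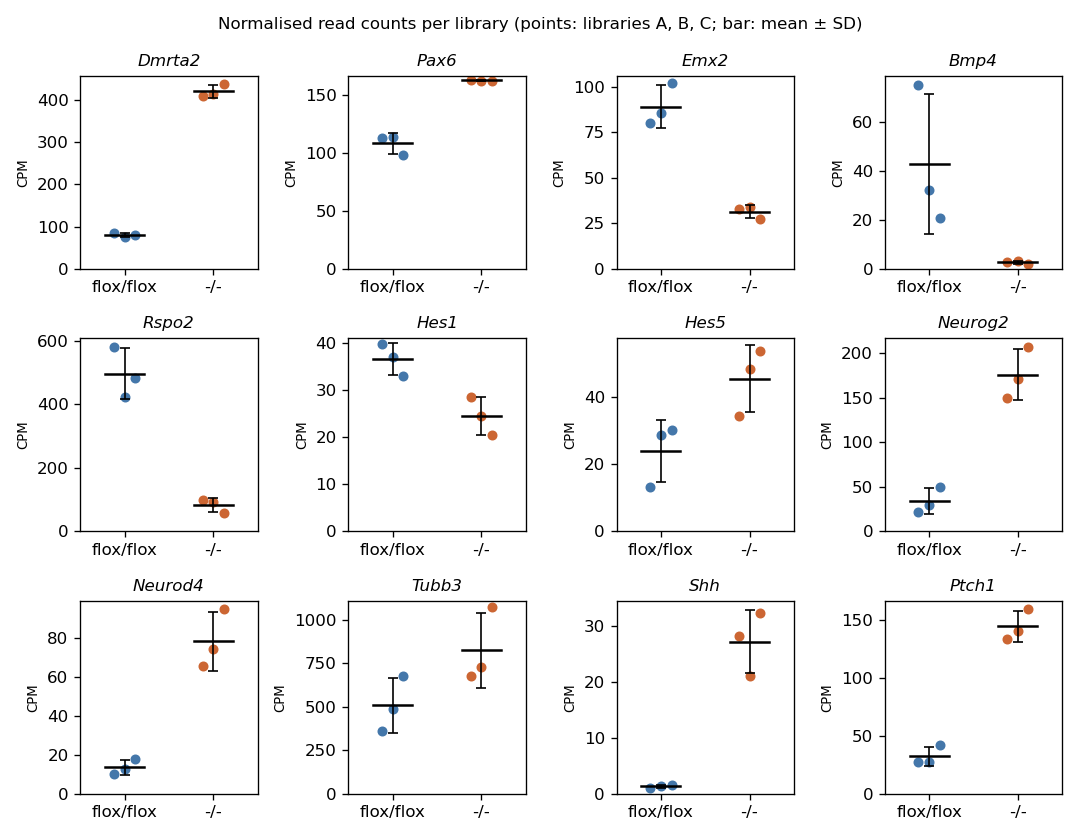
Normalised read counts (CPM, vertical axes) of 12 genes in the 3 flox/flox libraries (blue) and the 3 libraries labelled -/- (orange); points are libraries A, B and C from left to right, and bars show mean ± SD. Dmrta2 lies between 75.1 and 85.2 CPM in the flox/flox libraries and between 409 and 439 CPM in those labelled -/-, while the groups overlap for Tubb3, whose difference did not pass the threshold.

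Genes of chromosome 11 were shifted as a whole. Among 838 protein-coding genes of this chromosome with a mean of at least 10 CPM, the median log2 fold change was 0.57 (95% bootstrap interval 0.54 to 0.59), or 1.48-fold, and 82.8% rose. The medians of the other chromosomes lay between -0.07 and 0.04. The median of chromosome 11, taken against the mean of the control libraries, was 0.57, 0.56 and 0.56 in -/- A, B and C and -0.0045, -0.0035 and 0.0055 in flox/flox A, B and C. Over all tested genes, 947 of 1589 genes on chromosome 11 rose and 96 fell (61 without flox/flox B or without -/- B), so that it carried 25.7% of the rises with 7.73% of the tested genes. With an offset of 0.516, the median of all its tested genes minus that of all others at any level and biotype, taken out in an alternative chosen after seeing the data, 258 of its genes rose and 348 fell. Members of the lists that lie on chromosome 11 are named as such in what follows.

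**Figure D2:**
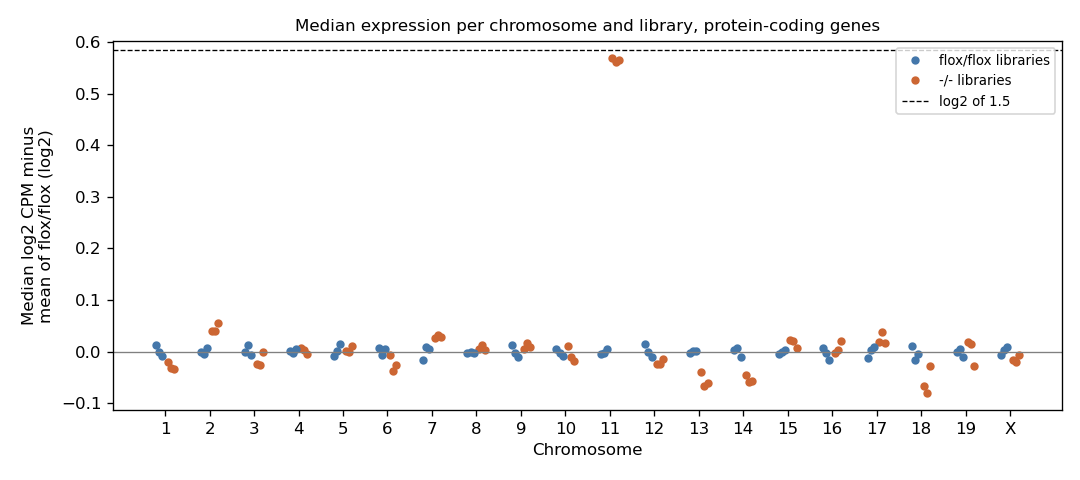
Median log2 CPM of protein-coding genes per chromosome (horizontal axis) and library, relative to the mean of the flox/flox libraries (vertical axis, log2); points are single libraries, blue for flox/flox and orange for those labelled -/-, and the dashed line is the log2 of 1.5. The 3 libraries labelled -/- stand between 0.56 and 0.57 on chromosome 11, and the medians of the fold changes on all other chromosomes lie between -0.07 and 0.04.

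The largest rises among the named genes were in S100g, which encodes a calcium-binding protein (4.98 ± 0.71, log2, SE, and 7.63 without flox/flox A, as the other 2 control libraries were at 0.0760 and 0.0398 CPM), Nap1l5 (4.75 ± 0.38), Plagl1 (4.65 ± 0.14), Nnat (4.58 ± 0.40) and Shh (4.41 ± 0.23). Nap1l5, Plagl1 and Nnat are imprinted genes expressed from the paternal allele. Nnat went from 65.1 ± 30.7 to 1553 ± 538 CPM (SD, n = 3) and Plagl1 from 5.89 ± 0.806 to 148 ± 18.5 CPM. They were followed by Sim1, a transcription factor of the hypothalamus (18.8-fold), Nsg2 on chromosome 11 (14.7-fold), Adamtsl1 (13.4-fold), Pitx1 (12.0-fold) and Acsbg1 (11.7-fold, and 20.5-fold without flox/flox C). The largest falls were in the desmosomal cadherin genes Dsg1b (-7.71 ± 0.94) and Dsg1a (-7.21 ± 0.90), near-identical copies whose reads may not be separable. Without flox/flox A these were -6.90 and -6.56, and without -/- A -8.89 and -8.43. Acpp fell 25.7-fold, the cation channel gene Trpm3 18.8-fold, the caveolin gene Cav1 17.4-fold, Ccdc3 17.1-fold, the BMP-induced homeobox gene Msx1 16.3-fold, Bmp4 16.1-fold, Synpo2l 15.5-fold and the protease gene Adamts15 15.1-fold. Without flox/flox A the falls of Trpm3, Msx1 and Bmp4 were 7.29-fold, 8.93-fold and 10.0-fold. Adjusted p in edgeR was between 2.0e-05 (Plagl1) and 0.00711 (Trpm3) for these 20 genes. Of the exonic bases of Ccdc3, 69.1% overlap another gene, as do 28.3% of those of Shh.

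Proneural and neurogenic factors, the transcription factors and regulators that commit progenitors to a neuronal fate, rose in 24 of 25 measured members (24 adjusted over the list alone), with a median log2 fold change of 1.36. Neurod4 rose 5.85-fold, Neurog1 3.21-fold, Eomes, a marker of intermediate progenitors, 2.28-fold and the antiproliferative gene Btg2 also 2.28-fold. The remaining member, Neurod2 (added, on chromosome 11), was at 0.619 and 0.757 CPM in the flox/flox libraries and those labelled -/-. By camera the list was higher, with an adjusted p of 1.56e-16, and adjusted p = 0.317 with an estimated correlation. Without flox/flox B the number of members that rose was 15, and the call for Eomes was lost without that library (adjusted p = 0.0952 in edgeR), without -/- B (0.0710) and without -/- C (0.0575), where the other alternatives gave values down to 0.000796. The log2 change of Eomes was 1.19 in the main fit and 1.07 without flox/flox B.

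Markers of postmitotic neurons rose in 26 of 30 members and fell in 0 (29 and 0 adjusted over the list alone), with a median of 0.99. Syt4, a synaptotagmin, rose 4.20-fold, and on chromosome 11 Nsg2 rose 14.7-fold and Mapt, the gene of the microtubule protein tau, 3.46-fold. Tubb3, neuronal beta-tubulin, was at 508 ± 160 and 826 ± 217 CPM (SD, n = 3), a log2 difference of 0.70 ± 0.25 that did not pass (adjusted p = 0.0663, edgeR). With the column letter as a block its adjusted p was 0.000362, and over all alternatives it lay between 0.000362 and 0.172, passing also without flox/flox C (0.0164), with DESeq2 (0.0145) and with no filter (0.0276). L1cam, Dpysl3 and Gng3 (added) also did not pass, with log2 differences of 0.73, 0.69 and 0.57. With the column letter as a block all 30 members rose, these genes included. The list was higher by camera (adjusted p = 1.81e-09; adjusted p = 0.410 with an estimated correlation), and 23 of the 26 rises lay outside chromosome 11. Without flox/flox B, 11 members rose. The mean log2 level of the list relative to the flox/flox mean was -0.33, -0.04 and 0.37 in flox/flox A, B and C and 0.80, 0.95 and 1.54 in -/- A, B and C.

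Genes of the cortical hem and choroid plexus, the signalling centre and secretory tissue at the dorsal midline of the telencephalon, fell in 18 of 23 members and rose in 0 (19 and 1 adjusted over the list alone). Their median was -2.10. Rspo2 and Rspo3, secreted enhancers of Wnt signalling, fell from 496 ± 79.6 to 82.4 ± 21.1 CPM and from 177 ± 39.1 to 47.1 ± 2.28 CPM (SD, n = 3), and Lmx1a, a transcription factor of the roof plate, fell 8.22-fold. The 5 members that did not pass were Wnt7b, Zic1, Axin2 (on chromosome 11), Ttr and Wnt2b (added), with log2 differences of 0.26, -0.53, -0.64, -2.28 and -0.10. Camera gave an adjusted p of 9.79e-15, and adjusted p = 0.308 with an estimated correlation. Without flox/flox C, 1 member rose, as with the column letter as a block, where 20 fell. The mean log2 level of the list differed within the control group too, at 0.56, -0.20 and -0.37 in flox/flox A, B and C, and was -1.61, -1.76 and -2.02 in -/- A, B and C. BMP targets fell in 6 of 11 members and rose in 0 (7 and 1 adjusted over the list alone), with a median of -2.10. Among them Id3, an inhibitor of bHLH factors, fell 7.70-fold, the pseudoreceptor gene Bambi 5.49-fold and Smad6, an inhibitor of BMP signalling, 5.23-fold. Without flox/flox A or flox/flox C, and with the column letter as a block, 1 BMP target rose. The list was lower by camera, with an adjusted p of 5.85e-06, and adjusted p = 0.190 with an estimated correlation.

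Wnt targets fell in 5 of 15 members and rose in 2 (6 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.201). On chromosome 11 lie 5 of the 15 members, among them Axin2, and all the calls lie outside it. With the chromosome 11 offset 2 rose and 7 fell, and the camera adjusted p was 0.0549. Lef1, a transcription factor of the pathway, fell 1.49-fold, Apcdd1 1.86-fold and the Wnt antagonist gene Wif1 11.8-fold from 1.06 CPM, beside Sp5 and Ccnd2 (added). The antagonist gene Dkk1 and Lgr5, a receptor of R-spondins, rose 2.18-fold and 1.81-fold from levels under 3 CPM. Neither rise was called without flox/flox B, 1 member rose when any single library labelled -/- was left out, and 2 members fell without -/- B. With the column letter as a block 5 rose and 9 fell.

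Transcription factors of the dorsal telencephalon split, with 9 of 21 members rising and 9 falling (9 and 10 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.199). Emx2 and Emx1, homeobox genes of the cortical primordium, fell from 89.0 ± 11.6 to 31.3 ± 3.74 CPM and from 4.47 ± 1.57 to 0.437 ± 0.207 CPM (SD, n = 3), and Fezf2 fell 2.30-fold. Pax6, a regulator of cortical progenitors, rose from 108 ± 8.96 to 162 ± 0.381 CPM, and Fezf1 rose 1.66-fold. Neurog2 and Eomes, also among the rises, are counted among the proneural factors too. Lhx2, a selector gene of the cortex, was at 69.4 ± 33.8 and 66.8 ± 13.1 CPM and did not pass (log2 difference -0.05 ± 0.32, adjusted p = 0.914, edgeR). Its sign changed without flox/flox C (0.41), without -/- A (0.05) and without -/- B (0.01). In the Dmrt family list, which contains Dmrta2 itself, 2 of 7 members rose and 1 fell, the same adjusted over the list alone. Dmrta1 rose 1.53-fold and Dmrtc1a fell 5.57-fold, and 2 members fell without flox/flox C. The camera adjusted p was 0.0110, with adjusted p = 0.308 with an estimated correlation, 0.0647 with the column letter as a block and 0.0670 without flox/flox C.

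Ventral telencephalic genes rose in 8 of 19 members and fell in 1 (8 and 2 adjusted over the list alone), with a median of 0.97. Of the 22 genes listed, Gsx2, Nkx2-1 and Lhx8 (added) had too few reads to be tested, at 65, 3 and 37 over the 6 libraries. Beside Shh, Slc32a1, the vesicular transporter of inhibitory neurotransmitters, rose from 0.159 ± 0.0362 to 1.32 ± 0.499 CPM (SD, n = 3), and the homeobox gene Vax1 fell from 2.68 ± 2.15 to 0.0551 ± 0.0405 CPM, a log2 change of -5.45 (-4.61 without flox/flox A and -6.24 without -/- A), and 2 members fell without flox/flox C or -/- C. With the column letter as a block 10 rose and 2 fell. The mean log2 level of the list relative to the flox/flox mean was 0.688, 0.707 and 1.398 in -/- A, B and C. The list was higher by camera (adjusted p = 0.00231; adjusted p = 0.410 with an estimated correlation). Hedgehog targets rose in 5 of 8 members and fell in 0, the same adjusted over the list alone, with a median of 0.90. By the protocol, the Hedgehog pathway inhibitor cyclopamine was in the medium of both groups when RNA was taken. Ptch1, the Hedgehog receptor and a direct target of the pathway, rose from 32.2 ± 8.39 to 145 ± 13.6 CPM, the ventral homeobox gene Nkx6-1 4.45-fold, Hhip 3.48-fold and Foxa2 2.07-fold, beside Gli1 (added). Camera gave an adjusted p of 0.00231, and adjusted p = 0.308 with an estimated correlation. Without flox/flox B or without -/- B, 3 of the Hedgehog targets rose.

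Genes of the diencephalon, midbrain, hindbrain and spinal cord fell in 14 of 28 members and rose in 4 (17 and 5 adjusted over the list alone), with a median of -0.75. The midbrain and hindbrain genes Pax2 and En2 fell 13.1-fold and 3.91-fold, and Hoxc4 fell 9.55-fold from 0.590 CPM. Those that rose included Tcf7l2, Lhx9 and Barhl2 (added), of which Lhx9, a transcription factor of the thalamic region, went from 29.1 ± 11.7 to 115 ± 38.1 CPM (SD, n = 3). Of the 14 falls, 3 were on chromosome 11, leaving 11. With the column letter as a block 4 rose and 18 fell. The list was lower by camera (adjusted p = 0.00151; adjusted p = 0.190 with an estimated correlation). Eye field and retina genes fell in 5 of 11 members and rose in 0, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0615) but did without flox/flox B (0.0171), flox/flox C (0.0112) or -/- C (0.0347). The 5 were Otx2, a head patterning gene that fell 2.47-fold, Mitf, Aldh1a3, Pou4f2 and Aldh1a1 (the last 2 added), and all but Otx2 were at most 3.12 CPM on average in the flox/flox libraries.

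Markers of Cajal-Retzius cells, early neurons that arise in part from the hem, rose in 9 of 14 members and fell in 3, the same adjusted over the list alone. Of the rises, Nhlh2, and Ebf2 and Tbr1 (added), are also counted among the proneural factors. Lhx5, Nhlh2 and Lhx1 (on chromosome 11) rose 3.50-fold, 3.32-fold and 4.64-fold. Emx2, Trp73 and Reln, which encodes the secreted protein reelin, fell, Trp73 from 24.7 ± 6.53 to 4.78 ± 1.56 CPM and Reln from 84.8 ± 11.3 to 50.6 ± 8.03 CPM (SD, n = 3). The list did not pass (camera adjusted p = 0.0760), but did with the column letter as a block (adjusted p = 4.08e-06) and without flox/flox C (0.00120), -/- A (0.0178) or -/- B (0.0367). Cortical layer neuron genes rose in 7 of 17 members and fell in 3 (8 and 3 adjusted over the list alone). Of these rises, Bhlhe22 and Tbr1 are counted among the proneural factors too. Bhlhe22 rose 11.4-fold and the neural POU factor gene Pou3f2 4.96-fold, while Bcl11b and Fezf2, factors of deep-layer projection neurons, fell 3.40-fold and 2.30-fold. This list did not pass either (camera adjusted p = 0.195) but did with the letter block (0.0273) and without flox/flox C (0.00820), and 4 of its members rose without flox/flox B.

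**Figure D3:**
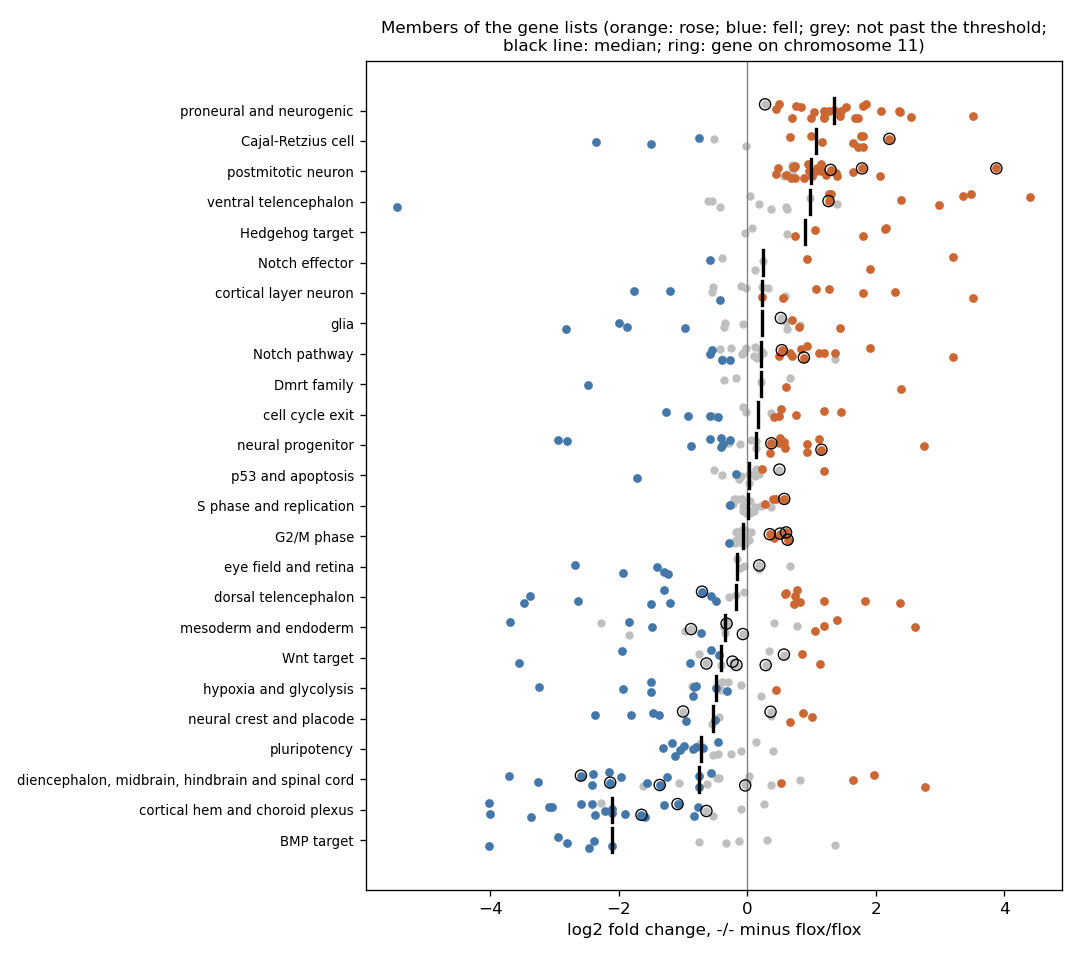
Log2 fold changes (horizontal axis, libraries labelled -/- minus flox/flox) of the tested members of the 25 gene lists (vertical axis); orange points rose, blue points fell, grey points did not pass the threshold, black lines are medians and rings mark genes on chromosome 11. The medians run from -2.10 for BMP targets and for cortical hem and choroid plexus to 1.36 for proneural and neurogenic factors.

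Neural progenitor markers went in both directions, with 11 of 24 members rising and 8 falling (11 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.299). The progenitor factor Sox2 fell from 235 ± 3.79 to 181 ± 4.13 CPM (SD, n = 3), a log2 change of -0.37 ± 0.05, Id1 fell 6.97-fold (4.57-fold without flox/flox A), and the endothelin receptor gene Ednrb rose 6.76-fold. Nes, the intermediate filament gene nestin, fell 1.20-fold with an adjusted p of 0.0459 in edgeR, which reached 0.165 without flox/flox B and was above the threshold without flox/flox A (0.115), -/- B (0.145) and -/- C (0.12) as well. Without chromosome 11 genes it was 0.0507, with the same log2 change (-0.27) as in the main fit, so the call was not lost through a smaller change. Without -/- B, 4 members fell, and without flox/flox B, 5 did. Hes1, a Notch effector that maintains progenitors, fell from 36.5 ± 3.43 to 24.5 ± 4.08 CPM, a log2 change of -0.57 ± 0.13 with an adjusted p of 0.0129 (edgeR). Its call was lost without -/- B (adjusted p = 0.0505), the highest value over its alternatives, which reached down to 0.000799.

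The effector Hes5 went the other way, from 23.9 ± 9.26 to 45.4 ± 9.89 CPM (SD, n = 3). Its log2 change of 0.92 ± 0.30 had an adjusted p of 0.0482 in edgeR, which lay between 0.000943 and 0.122 over its alternatives and above the threshold without flox/flox B (0.0785), -/- B (0.122) or -/- C (0.115), with the stricter filter (0.0515), without chromosome 11 genes (0.0522) and with the chromosome 11 offset (0.0513). In both settings for chromosome 11 its log2 change was the same as in the main fit, as the gene is on another chromosome, so the call was not lost through a smaller change. Notch pathway genes rose in 12 of 29 members and fell in 4 (13 and 5 adjusted over the list alone). With the column letter as a block 14 rose and 6 fell. Dll1, Dll3 and Hes6 (added), which are among the rises, are also in the proneural list. Notch1, the receptor, rose 2.17-fold, the feedback inhibitor gene Nrarp 3.78-fold, Heyl 9.22-fold to 4.22 CPM and the glycosyltransferase gene Rfng, on chromosome 11, 1.84-fold. Those that fell were Hes1, Numb and Numbl, which encode inhibitors of Notch, and Maml2 (added), a coactivator. Only 2 members fell when flox/flox B or any of the 3 libraries labelled -/- was left out, and the adjusted p of Numb reached 0.0892 without flox/flox B. The smaller list of Notch effectors rose in 3 of 7 members (Heyl, Nrarp and Hes5) and fell in 1 (Hes1; 0 without -/- B), the same adjusted over the list alone. Camera placed both lists higher, with adjusted p of 0.00231 for the pathway and 0.0356 for the effectors, and adjusted p = 0.308 with an estimated correlation for each. Exons of other genes overlap 79.4% of Nrarp and 31.8% of Hes5.

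Few cell cycle genes passed the threshold. Among S phase and replication genes 4 of 24 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.673), and among G2/M genes 5 of 24 rose and 1 fell, again the same (camera adjusted p = 0.816). The median of the G2/M list was -0.07 and its mean 0.03. Mki67, the proliferation marker, was at 379 ± 16.6 and 394 ± 43.5 CPM (SD, n = 3) and did not pass (adjusted p = 0.655, edgeR). Of the 5 G2/M genes that rose, Top2a, Birc5, Aurkb and Hmmr (added) lie on chromosome 11, as does Cdc6 in the S phase list. With the chromosome 11 offset the log2 changes of Top2a, Aurkb and Cdc6 were 0.09, 0.11 and 0.06 and did not pass, and 1 G2/M gene rose, whereas Ccnb2 (added) is on another chromosome. Clspn, E2f1 and Ccne2 (added) also rose in the S phase list, and the ribonucleotide reductase gene Rrm1 and the kinase gene Cdk1 fell 1.20-fold and 1.21-fold. In the S phase list, 1 member rose without flox/flox A, flox/flox B or -/- B, and in the G2/M list 3 rose without -/- A or -/- B. In both lists 0 members fell when -/- B or any single flox/flox library was left out, and 2 fell without -/- A. With the column letter as a block 4 rose and 2 fell in the S phase list, and 5 rose and 4 fell in the G2/M list. The adjusted p of Clspn, E2f1, Rrm1 and Cdk1 reached 0.0615, 0.0911, 0.0862 and 0.0826 in edgeR over left-out libraries.

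Genes of cell cycle exit rose in 6 of 14 members and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.155). Cdkn2c and Cdkn1b, inhibitors of cyclin-dependent kinases, rose 2.74-fold and 1.44-fold, while Cdkn1c, Cdkn2b, Cdkn2a (added) and the retinoblastoma gene Rb1 fell, Cdkn1c from 223 ± 29.5 to 149 ± 17.6 CPM (SD, n = 3). Cdkn2c lies near Dmrta2 on chromosome 4, next to Faf1, which also rose. In the p53 and apoptosis list 2 of 15 members rose (Btg2 and Bax) and 2 fell (Pmaip1 and Mdm2), or 1 and 1 adjusted over the list alone. That list did not pass (camera adjusted p = 0.472), and its median was 0.03 and its mean -0.03. Without -/- C, 4 members rose and 1 fell, and 1 rose when any other single library was left out. With the column letter as a block 3 rose and 3 fell. The call for Bax was lost when any single library but -/- C was left out and that for Mdm2 without each of the 6, and those for Btg2 and Pmaip1 were kept. In this list 1 member fell without flox/flox A, flox/flox B or -/- B.

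Genes of hypoxia and glycolysis fell in 9 of 17 members and rose in 1 (12 and 1 adjusted over the list alone), with a median of -0.49. The glucose transporter gene Slc2a3 fell from 297 ± 92.2 to 77.4 ± 19.6 CPM (SD, n = 3), Ndrg1 fell 2.82-fold and the adrenomedullin gene Adm 9.50-fold from 1.78 CPM, and Ddit4, an inhibitor of mTORC1, rose 1.36-fold (2 members rose without flox/flox A, and 2 rose and 12 fell with the column letter as a block). The list was lower by camera (adjusted p = 0.00231; adjusted p = 0.410 with an estimated correlation). Pluripotency genes fell in 9 of 16 members and rose in 0, the same adjusted over the list alone, with a median of -0.71. Esrrb, Utf1 and Tfcp2l1, factors of the mESC state, fell 1.98-fold, 2.07-fold and 2.19-fold from levels between 6.03 and 10.2 CPM. Camera gave an adjusted p of 0.00237, and adjusted p = 0.410 with an estimated correlation, and 5 members fell without flox/flox B, and 1 rose without flox/flox A. With the column letter as a block 1 rose and 10 fell.

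Markers of other cell types moved in both directions. In the mesoderm and endoderm list 4 of 19 members rose and 4 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.472). The endothelial receptor gene Kdr fell 12.9-fold, the collagen gene Col3a1 3.60-fold and the smooth muscle actin gene Acta2 2.80-fold, beside T (added). The endoderm factors Sox17 and Foxa2 rose 6.14-fold and 2.07-fold, beside Gata6 (added) and Eomes, which is also counted among the proneural factors. Without flox/flox B or without -/- B, 1 of these members rose, and without -/- A, 2 did, with the adjusted p of Foxa2 then at 0.0667. Neural crest and placode genes rose in 3 of 14 members (Tfap2a, Eya1 and Tfap2b) and fell in 6 (4 and 7 adjusted over the list alone; camera adjusted p = 0.163), and 1 rose without flox/flox B. The mesenchymal factors Snai2 and Prrx1 fell 3.53-fold and 2.76-fold. Glial genes rose in 3 of 14 members and fell in 4, the same adjusted over the list alone (camera adjusted p = 0.472). Nfia and Nfib, transcription factors of the switch to gliogenesis, fell 7.09-fold and 3.66-fold, beside Apoe and Cspg4 (added), and those that rose included Slc1a2 and Aldh1l1. The median of the glial list was 0.23 and its mean -0.21, and 0 of its members rose without flox/flox B and 5 without -/- C.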

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

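The column-letter block, the setting without chromosome 11 genes and the chromosome 11 offset were chosen after the results were seen, and the other settings before. The planned block on the replicate numbers of the labels was not run, as the columns carry letters, and the column letter was used as the block. It gave 8529 genes and moved 3 list calls, Cajal-Retzius cells to an adjusted p of 4.08e-06, cortical layer neurons to 0.0273 and the Dmrt family to 0.0647. Among the genes named by the rule it moved the call of Tubb3 and the sign of Lhx2 (log2 change 0.0315). It moved no other call of these genes or of a list. Further members of lists were called, as all 30 neuron markers rose, L1cam, Dpysl3 and Gng3 among them.

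The 7250 genes past the threshold fell to 3887 at an adjusted p under 0.01, with 1992 higher and 1895 lower. Leaving out single libraries gave 4717 (without flox/flox B) to 6846 genes (without flox/flox C), 2315 to 3510 higher and 2342 (without -/- B) to 3336 lower. Between 6809 and 7249 genes passed with other scalings or filters, 7240 with DESeq2 and 7169 with limma-voom. Of the 7250 genes, 6921 were shared with DESeq2, 7075 with limma-voom and 4635 with the setting without flox/flox B, with 0 in the opposite direction in each. Without chromosome 11 genes 6028 passed, 44.0% of them higher, and with the offset 6683, with 24 shared genes in the opposite direction. Leaving out libraries or genes gives the test less to work with by construction, and the cause of the other differences was not tested. Small changes can be missed at this depth with 3 libraries per group, as 68.7% of 1.5-fold changes were recovered in simulation, which did not separate depth from the number of libraries.

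With an estimated correlation camera called 0 of the 25 lists, 3 at an unadjusted p under 0.05, against 12 at the preset correlation and 17 by fry. The adjusted p was then 0.190 for diencephalon to spinal cord and BMP targets, 0.308 for the Notch pathway, Notch effectors, cortical hem and choroid plexus, Hedgehog targets and Dmrt family, 0.317 for proneural factors, and 0.410 for postmitotic neurons, ventral telencephalon, pluripotency and hypoxia. Under all other settings 10 of these 12 lists stayed past the threshold. The exceptions were Notch effectors with the stricter filter (0.0528) and the Dmrt family with the letter block and without flox/flox C (0.0670). Over left-out libraries the Dmrt family ran from 0.00663 to that value. Fry added neural progenitors (0.00964), dorsal telencephalon (0.0344), eye field (0.0193), cell cycle exit (0.0193) and neural crest (0.0418). Without a filter, eye field (0.0381) and Cajal-Retzius cells (0.0127) passed, and the latter also with the chromosome 11 offset (0.0355). Over left-out libraries the adjusted p ran from 0.0112 to 0.0866 for eye field, 0.00120 to 0.188 for Cajal-Retzius cells and 0.00820 to 0.330 for cortical layer neurons, each lowest without flox/flox C.

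Directions of some lists that did not pass were reversed when a library was left out. Without -/- A the S phase (range 0.119 to 0.813), G2/M (0.171 to 0.905) and p53 lists (0.113 to 0.991) turned lower, and without -/- C mesoderm and endoderm (0.240 to 0.938) turned higher. The G2/M list also turned lower without chromosome 11 genes (0.530) and with the offset (0.603), where its 4 chromosome 11 members are left out or lowered. Of 1907 values of 128 named genes under alternatives, 1821 kept their direction and side of the threshold. Those that reversed were Lhx2 with limma-voom (0.0405) and without single libraries (-0.31 to 0.41, the highest without flox/flox C), Mki67 without -/- A (-0.0145, range up to 0.15) and Birc5 with the offset (-0.0032). Leaving out flox/flox B ended the most calls among named genes (18). For Dmrta2 the log2 change lay between 2.36 and 2.45 over left-out libraries, and its highest adjusted p over all alternatives was 0.000586. Where not stated, the cause was not tested.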

Other observations

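Chosen only after the results were seen were the tests of a single wrong label, of reads from Dmrta2os, of exchanged group labels, of a few strongly changed genes on chromosome 11, of a difference in imprinting, of an extra chromosome 11 acting on genes elsewhere and, in its revised form, of more neurons. The list of imprinted genes was written after the values of 49 of its 53 genes had been seen. Imprinted genes, which are expressed from 1 parental allele, changed widely: of 53 listed, 51 were tested and 40 (78.4%) passed the threshold. Among those expressed from the paternal allele 19 of 28 rose and 5 fell, with a median log2 change of 0.81, and among those expressed from the maternal allele 7 of 23 rose and 9 fell, with a median of -0.40. Of the rises, paternally expressed Zrsr1 and maternally expressed Commd1 lie on chromosome 11. Exon overlaps were looked up only for the genes named by the rule. Whether other imprinted genes share reads, such as Copg2 (1.03, maternal) and Mest (1.13, paternal) on chromosome 6, was not checked. Plagl1 and Nnat rose 25.1-fold and 23.9-fold, Dlk1, a Notch ligand relative, rose from 9.84 ± 2.86 to 72.2 ± 27.7 CPM (SD, n = 3), and Impact from 90.2 ± 1.29 to 134 ± 4.74 CPM. Igf2r, a maternally expressed receptor that clears the growth factor Igf2, fell from 318 ± 67.9 to 46.5 ± 3.37 CPM, Grb10 (on chromosome 11) fell 12.2-fold, and Zim1 and Klf14 fell 7.08-fold and 9.89-fold. Others moved opposite to the median of their class, as H19 rose 6.47-fold and Igf2 and Slc38a4 fell 3.49-fold and 4.48-fold.

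The median absolute log2 change of the imprinted genes was 0.96, where 10000 random lists matched on expression had a median of 0.27 and a 95th percentile of 0.33. The list holds the genes that prompted it, so a first list was used as a check, typed before its values were looked up and taken without the 7 genes noticed by then: 33 of its 45 tested genes passed, with a median of 0.85 against a 95th percentile of 0.34. Without chromosome 11 the median of the later list was 0.94 over 48 genes, and that of the first 0.85 over 43, both at percentile 100 of matched lists. Most of the listed genes thus lie elsewhere and changed without a dosage difference of their own chromosome. An effect of the chromosome 11 shift on genes elsewhere cannot be told apart from one of the genotype, as all 3 libraries labelled -/- come from the line with the shift (median 0.937 outside that chromosome). More neurons in the libraries labelled -/- would leave a change predictable from the slope on the neuron list within groups. This predicted a median share of 0.142 of the observed change (95% bootstrap interval over genes -0.0152 to 0.381). The share was 0.739 for proneural genes outside that list and 1.03 for members of it held out of the score. These values argue against more neurons as the whole cause, although for 10 of the 40 genes the share was at least 0.5. The interval resampled the 40 genes, some of which share a cluster. It does not hold the error of the slope, which rests on 3 libraries per group. A difference in imprinting between the lines stays open. In the first list without the 7 genes, with 1 value per gene cluster and class, the mean of paternally expressed genes was 0.52 above that of maternally expressed ones. With 16 and 11 values the two-sided permutation p was 0.330 (100000 resamples), which does not show a shared direction. The permutation treated all values as independent, although some clusters hold both classes, so a difference within clusters was not tested. A difference in imprinting could also raise some clusters and lower others. As each genotype is 1 line, such a difference may belong to the line and not to Dmrta2, and methylation and allele-specific reads were not analysed here.

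The shift of chromosome 11 was 1.48-fold, where 3 copies against 2 would give 1.5-fold. A correction for GC content and gene length left its median at 0.593 (log2), and 91.4% of its genes lay above the median of the other autosomes, which argues against such a bias and against a few strongly changed genes. An extra copy of chromosome 11 in the line labelled -/- is a candidate explanation, as the lowest median among 10 equal parts of the chromosome was 0.449 and all 3 libraries showed the shift. Genomic DNA was not analysed here, and whether some or all cells would carry it stays open. With 1 line per genotype, nothing here ties the shift to Dmrta2, and changes of other genes may follow from it.

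The lowest Dmrta2 level in a library labelled -/- was 4.80 times the highest in a flox/flox library, which argues against a single wrong label. Exons of Dmrta2os cover 0 bases of the exons of Dmrta2, so reads of its annotated exons (GENCODE M21), themselves 8.41-fold higher, do not account for the count. Transcription of the antisense gene beyond these exons was not tested, nor another annotation. Whether the groups carry each other's labels cannot be told apart from a true rise of 2.40 (log2), because the table has no counts per exon and no value independent of the labels. A release of the gene from repression by its own product could also raise the count of the remaining transcript, and this was not tested.

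Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave 7250 genes past the threshold in edgeR, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 9327 genes and the others at most 872. The splits are too few for a share under 0.05. Each of the other splits mixes the lines, which adds the difference between lines to the spread within its groups. Low counts there follow from that, so the comparison says nothing on the cause of the difference.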
